A study of Homo sapiens with 10 samples.

How the data were processed

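Chromatin accessibility had been measured by Omni-ATAC-seq in human mesenchymal stem cells under chondrogenic differentiation, held either in sliding hydrogels (SG) or in chemical hydrogels (CG). Per the labels' protocols, transposition was done with the cells still inside the gels for 1 h at 37 °C. The gels were crushed afterwards, and libraries were amplified with 5 PCR cycles. No measurement used here separates access of the enzyme through each gel from accessibility of the chromatin, so any difference between SG and CG may hold both. The 10 libraries formed 4 groups by gel and time: CG and SG at 16 h (n = 2 each) and CG and SG at 48 h (n = 3 each). Groups, replicate numbers and times were taken from the sample titles. Nothing in the labels states that replicates came from separate cultures or donors, so each p measures only the spread between these samples, which may be technical.

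Per the submitters' processing notes, reads were aligned with Bowtie2 and handled with SAMtools, and peaks were called with MACS2, on the builds GRCh38.p5 and hg38. Any count tables or tests made by the submitters were not used here. Tool versions and options are not given in the sources used here. Peak names carry 1 library each, so peaks had been called per library. The deposited score was 10 times the −log10 q, as a whole number. The deposited ratio (fold enrichment) compared fragments at the peak summit with the local background of the same library. The deposited −log10 p and −log10 q values (p-value and q-value) described the summit within its own library. These per-peak values are the authors' own and were compared only within a list.

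Peaks on chromosomes 1 to 22 and X were counted as distinct intervals. The lowest deposited −log10 q per list was 1.30 to 1.31, a q threshold of 0.05. Fragments at each summit and in its local background were recovered from the deposited fold and p, with a pseudocount of 1 and the Poisson upper tail. This gave whole numbers at 100% of summits (tolerance 0.0002 in −log10 p). The lowest local background served as the measure of depth, and ranged from 0.413 to 1.21 fragments per library. Median summits held 12 to 16 fragments, which limits how finely weak peaks can be told from background.

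Gene coordinates came from the RefSeq table of GRCh38.p14, with 19974 protein-coding genes. It carries neither strand nor sequence, so some steps departed from the design. Promoters became gene-end windows of 1 kb on each side of both gene ends. Averaged over the 10 libraries, 4.59% of genes longer than 20 kb had a peak at both ends within a library. Genes were named by the nearest gene end, where the design had the nearest start site. Searches for 26 fixed motif consensus sequences were not run. A gene locus was the gene body with 10 kb on each side. Regions were the merged peaks of all 10 libraries, kept where at least 2 libraries had a peak overlapping by 1 bp or more. A separated region had a peak in every library of 1 group and in none of the other. Leaving out a library loosens this rule, so the counts then tend to rise whichever library is dropped.

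Numbers of peaks, covered length and genes with a gene-end peak were compared as log2 values, and shares as percentages. All p came from exact two-sided permutation tests of mean differences with a threshold of 0.05. Gel labels were permuted within time (120 arrangements, smallest possible p 0.0167, or 20 with smallest p 0.1 at 48 h and 6 with smallest p 0.333 at 16 h). For the difference between the gel effects at 48 h and 16 h, this p is exact only where the gel has no effect at either time. It is therefore not a test of equal effects alone. Time labels were permuted within gel (100 arrangements, smallest p 0.01). Counts of separated regions were compared with other splits of the same libraries. Similarity was the Jaccard index of covered bases.

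Before the data were examined, 29 gene lists with 627 genes were fixed. They covered chondrogenic, hypertrophic and osteogenic, adipogenic, mesenchymal stromal, endothelial, epithelial, haematopoietic, neural and myogenic markers. They also covered integrins, mechanosensitive channels, YAP/TAZ, nuclear envelope, AP-1, TGF-beta, BMP, WNT, and FGF with hedgehog and Notch. The remaining lists were HOX patterning, matrix proteases, hypoxia, inflammation, glucocorticoid response, apoptosis and p53, cell cycle, histone acetylation, histone methylation, and ubiquitously expressed genes. The values of 1 further list and of 1 gene are not reported here. For each list, peaks per locus were divided by the mean of all protein-coding genes of the same library, taken as log2, tested, and corrected with the Benjamini-Hochberg method over the lists. Single genes were tested on the same ratio without log2, corrected over all genes with a peak and also over the list alone.

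Genes were named by a rule fixed before the data were examined, except that gene ends replaced the start sites of the rule. SOX9, ACAN, COL2A1, RUNX2, PPARG and LMNA were always named. Separated regions were ranked by the median percentile of their strongest peak within the own lists. In each gel comparison the 6 highest ranked per direction were named, as were up to 10 per direction whose nearest gene end belonged to a fixed list. Between the times, the limit was 4 for each. Genes were assigned within 50 kb, and genes that decide sex or are Y-linked were left out. Distances are to the nearer gene end, which may be the start or the far end of the gene.

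The tests, the named-genes rule and most alternatives were chosen before the data were examined, apart from the use of gene ends for start sites. These alternatives were a strict threshold (−log10 q of at least 5), equal list length (the 28067 strongest peaks of every library), each library left out in turn, replicate number as a block, and a stricter overlap (summit inside the region and 50% covered). The others were regions in at least 3 libraries, windows of 500 bp, loci with 50 kb margins, and chromosomes 1 to 22 only. After the data were examined, scaling to the lowest background was added, with fragments and background multiplied down to the shallowest library and peaks kept at −log10 p of at least 4. A second form measured depth per bp of the shortest peak of each library. Scaled lists were also run without each library in turn.

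The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for plots. They were tested on simulated data, in which 100% of pileups and of planted separated regions were recovered. A planted loss of peaks returned a log2 change of −0.51 (exact permutation p = 0.0167). A list with a planted halving returned −1.19 (exact permutation p = 0.0167), and 2 of the 28 other lists had p of 0.05 or less.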

Results

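The data were lists of accessible regions from CG and SG cultures at 16 h and 48 h. CG replicates 1 and 2 at 16 h held 45948 and 47456 peaks. SG replicates 1 and 2 at 16 h held 51239 and 64820. At 48 h, CG replicates 1 to 3 held 65225, 39527 and 59772 peaks, and SG replicates 1 to 3 held 52184, 50938 and 28067. Background depth in fragments was 0.427 and 0.413 in CG and 0.543 and 0.837 in SG at 16 h. It was 0.762, 0.575 and 0.831 in CG and 1.07, 1.21 and 0.618 in SG at 48 h. SG replicate 3 at 48 h stood apart from the rest, with a mean Jaccard index of 0.339 to the other 9 libraries, against 0.438 to 0.499 for each of those.

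Accessibility was shared between the gels at most gene-end sites. Of 68118 regions found in at least 2 libraries, 19155 (28.1%) had a peak in all 10. Of these constitutive regions, 45.4% lay within 1 kb of a gene end, against 19.7% of all 68118. A gene-end peak was present in all 10 libraries at 9881 protein-coding genes and in no library at 5510.

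At 16 h, SG libraries held 58030 ± 9603 peaks and CG libraries 46702 ± 1066 (mean ± SD, n = 2 each). At 48 h the means were 43730 ± 13579 in SG and 54841 ± 13540 in CG (n = 3 each). The log2 ratio of SG to CG was 0.30 at 16 h (exact two-sided permutation p = 0.333, the smallest possible). It was −0.35 at 48 h (exact permutation p = 0.5, smallest possible 0.1) and −0.09 over both times (exact permutation p = 0.75). Without SG replicate 3 the 48 h ratio was −0.06 and the ratio over both times was 0.10. Without CG replicate 1 at 48 h the ratio over both times was 0.02. The difference between the gel effects at 48 h and 16 h was −0.65 (exact permutation p = 0.167). It was −0.87 without CG replicate 2 at 48 h (exact permutation p = 0.05).

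Peaks covered 23.5 ± 7.23 Mb in SG and 20.6 ± 1.19 Mb in CG at 16 h (n = 2 each), and 16.8 ± 7.07 Mb in SG and 20.6 ± 5.20 Mb in CG at 48 h (n = 3 each). The log2 ratios of covered length were 0.15 at 16 h (exact permutation p = 1), −0.37 at 48 h (p = 0.5) and −0.16 over both times (p = 0.7). Without SG replicate 2 at 16 h the ratio at that time was −0.17. Without SG replicate 3 at 48 h the ratios were 0.05 at 48 h and 0.10 over both times.

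After scaling to the lowest background, an alternative chosen after the data were examined, SG at 48 h held 29816 ± 4693 peaks and CG 44931 ± 9240 (n = 3 each). All 3 SG libraries (25285 to 34655) lay below all 3 CG libraries (35571 to 54046). This log2 ratio of −0.58 had the smallest p that 3 against 3 allows (exact permutation p = 0.1). At 16 h the scaled means were 49402 ± 2307 in SG and 46143 ± 1055 in CG (n = 2 each), a log2 ratio of 0.10 (exact permutation p = 0.333). The difference between the gel effects on scaled peak number at 48 h and 16 h was −0.68 (exact permutation p = 0.0167). With depth measured per bp of the shortest peak, this difference was −0.66 (exact permutation p = 0.1), and the 16 h log2 ratio was −0.06. Over both times the log2 ratio was −0.31 on lists scaled to the lowest background (exact permutation p = 0.167). With depth per bp of the shortest peak it was −0.45 (exact permutation p = 0.05).

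**Figure D1:**
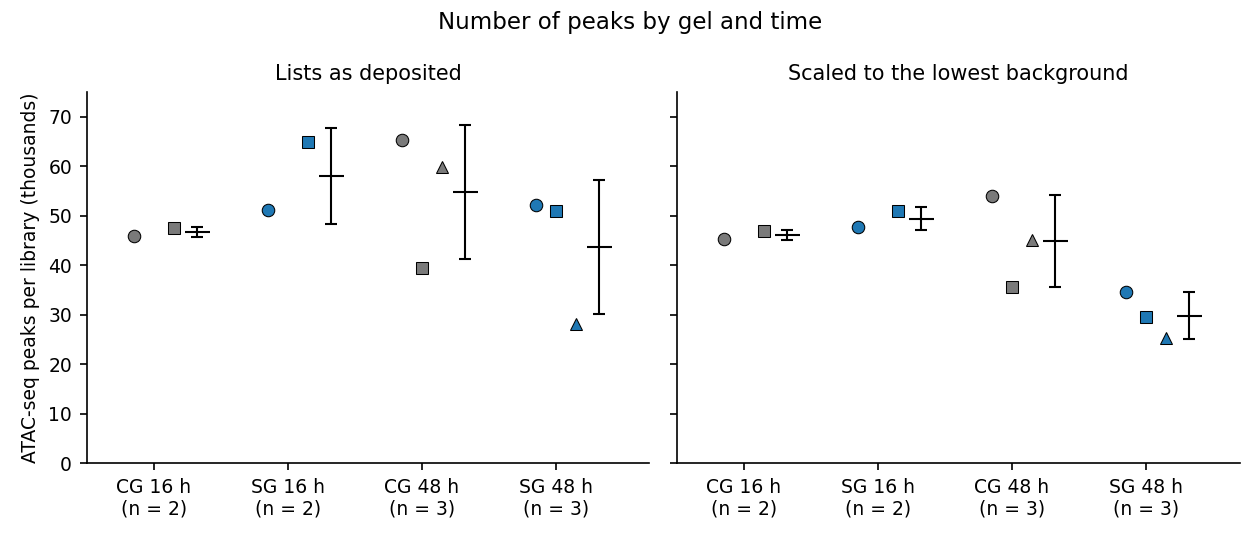
Number of peaks per library (axis in units of 1000), as deposited (left) and scaled to the lowest background (right), for CG (grey) and SG (blue) at 16 h (n = 2 each) and 48 h (n = 3 each). Circles, squares and triangles are replicates 1, 2 and 3, and bars with whiskers are means ± SD; on the right, SG at 48 h spans 25285 to 34655 and CG at 48 h 35571 to 54046.

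The locus of RUNX2, a regulator of hypertrophy and bone formation, held 8.33 ± 2.08 peaks in SG and 13 ± 3 in CG at 48 h (n = 3 each). At 16 h it held 11.5 ± 0.707 in SG and 11 ± 0 in CG (n = 2 each). SOX9, which directs chondrocyte formation, held 1.33 ± 0.577 peaks in SG and 2.33 ± 0.577 in CG at 48 h, and 2.5 ± 0.707 and 3 ± 0 at 16 h. Divided by the mean of all genes in the same library, the SG minus CG difference over both times was −1.01 for RUNX2 (exact permutation p = 0.0167, adjusted p = 1). By this measure every SG library lay below every CG library of its time at RUNX2. At 16 h that order came from the division alone, since the counts were 11 and 12 in SG and 11 and 11 in CG. For SOX9 the difference was −0.340 (exact permutation p = 0.0333, adjusted p = 1), with all SG below all CG libraries at 16 h alone. Its counts at 16 h were 3 and 2 in SG and 3 and 3 in CG, so this order also rests on the division. Of the 20 ubiquitously expressed genes, 12 lay below in the same way at 16 h and 1 above. Neither passed the correction over 18215 genes. After scaling, the difference was −0.891 for RUNX2 (exact permutation p = 0.1) and −0.272 for SOX9 (exact permutation p = 0.183). A gene-end peak was present at both genes in all 10 libraries.

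ACAN and COL2A1, which encode aggrecan and type II collagen of cartilage matrix, had no gene-end peak in any of the 10 libraries. The ACAN locus held 3.5 ± 0.707 peaks in SG and 2 ± 1.41 in CG at 16 h (n = 2 each), and 2 ± 1 and 2.67 ± 0.577 at 48 h (n = 3 each). COL2A1 held 2 ± 0 in SG and 2.5 ± 0.707 in CG at 16 h, and 1.67 ± 0.577 in each gel at 48 h. PPARG, an adipogenic regulator, held 7.5 ± 2.12 in SG and 5.5 ± 0.707 in CG at 16 h, and 3.67 ± 3.51 and 5 ± 2.65 at 48 h. LMNA, which encodes nuclear lamins, held 10.5 ± 0.707 in SG and 10.5 ± 2.12 in CG at 16 h, and 9 ± 2.65 and 10.7 ± 2.52 at 48 h. PPARG and LMNA each had a gene-end peak in 8 of 10 libraries. Exact permutation tests over both times gave p = 0.8 for ACAN, 0.55 for COL2A1, 0.917 for PPARG and 0.417 for LMNA.

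**Figure D2:**
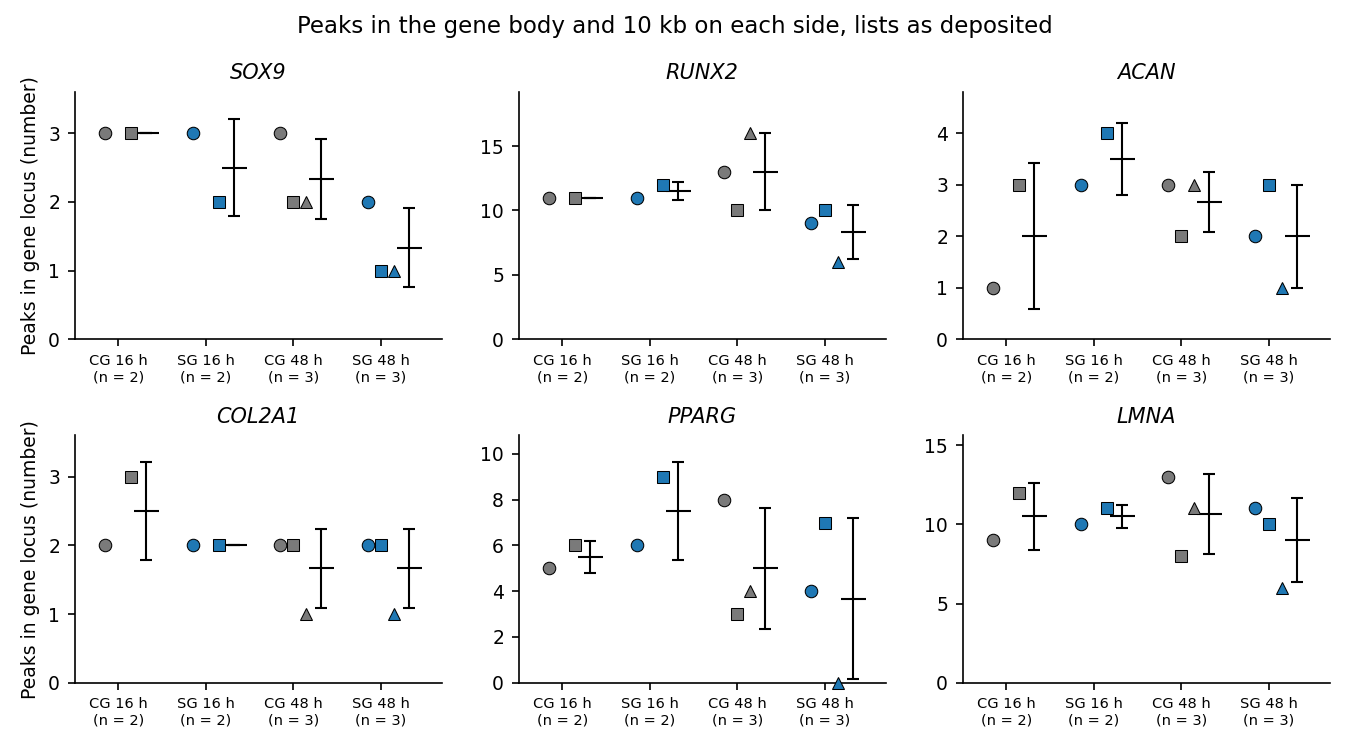
Number of peaks in the gene body and 10 kb on each side for SOX9, RUNX2, ACAN, COL2A1, PPARG and LMNA in CG (grey) and SG (blue) at 16 h (n = 2 each) and 48 h (n = 3 each). Circles, squares and triangles are replicates 1, 2 and 3, with means ± SD beside them; RUNX2 spans 6 to 10 peaks in SG and 10 to 16 in CG at 48 h.

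At 48 h, 641 regions had a peak in all 3 CG and no SG libraries, and 54 had a peak in all 3 SG and no CG libraries. The highest ranked CG region lay 42930 bp from a gene end of MRTFB, an actin-regulated transcription cofactor (hg38, chromosome 16, 14309710 to 14310177, outside gene bodies). It was followed by regions inside RAPGEF1 (chromosome 9, 131591257 to 131591569) and TLK2 (chromosome 17, 62614243 to 62614614), and by regions assigned to NPAS2, IWS1 and DTD1. Among the fixed lists, CG regions lay inside the alpha-actinin gene ACTN4 (chromosome 19, 38657796 to 38658097), the glycolytic regulator PFKFB3 (chromosome 10, 6300080 to 6300592) and the acetyltransferase gene CREBBP (chromosome 16, 3849479 to 3849970). Another lay 4656 bp from a gene end of WNT5B (chromosome 12, 1611833 to 1612400). Further CG regions were assigned to TRPC6, DUSP1, ADAMTS1 and KLF9, and to the epithelial markers EPCAM and CDH1. Of these named CG regions, only those of MRTFB, RAPGEF1 and CDH1 had a peak in no SG library at 16 h. The TLK2, NPAS2 and CREBBP regions had a peak in 2 SG and 2 CG libraries at 16 h. The ADAMTS1 region had one in 2 SG and 0 CG libraries at 16 h, the reverse order. Chosen after their values were seen, CG regions also lay 194 bp from a gene end of SOX9 (chromosome 17, 72126611 to 72127346) and 5107 bp from one of RUNX2 (chromosome 6, 45556190 to 45556655). Without strand, these ends were not told apart as start or far end, so neither region can be read as a promoter. Both genes had a gene-end peak in all 10 libraries. The SG regions were assigned to TTC34, CTIF, MYOC, MXRA7, EEF2 and LCLAT1, and to the stress response factor ATF3 (chromosome 1, 212567013 to 212567444, inside the gene). Of these, only the CTIF and EEF2 regions had a peak in no CG library at 16 h, and the MXRA7 region had one in 2 SG and 2 CG libraries.

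Of the CG regions at 48 h, 5.62% lay at gene ends, and of the SG regions 14.8%. The 695 separated regions compare with up to 2666 in another split of the same 6 libraries, and 4 of the 10 splits reached 695, too few splits for a share under 0.05. With 1 library left out the rule for a separated region is looser, so counts tend to rise. The SG count was 711 without SG replicate 3, 144 without SG replicate 1 and 138 without SG replicate 2. It was 196 without CG replicate 1 and 127 without CG replicate 3. The CG count was 4304 without CG replicate 2, 968 without CG replicate 1 and 1156 without CG replicate 3. It was 1695 without SG replicate 1 and 1370 without SG replicate 2. Scaling to the lowest background gave 15 SG and 1503 CG regions (15 to 94 and 1503 to 6298 with 1 library left out), and 11 of the 16 named CG regions and 4 of the 7 named SG regions remained separated. Under the strict threshold 6 of the 16 and 2 of the 7 remained, and with equal list length 4 of each.

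At 16 h, 3775 regions had a peak in both SG and no CG libraries, and 689 had the reverse. The highest ranked SG regions were assigned to SMARCD2, PARK7, PLEKHM1, PLEKHG4B, B3GALT5 and LMOD1. At 48 h the PLEKHG4B region had a peak in 3 SG and 3 CG libraries, SMARCD2 in 0 SG and 2 CG, and B3GALT5 in none. Among the fixed lists, an SG region lay 1348 bp from a gene end of the stromal chemokine gene CXCL12 (hg38, chromosome 10, 44386446 to 44386995). Others lay inside the myosin gene MYH9 (chromosome 22, 36286418 to 36286940) and inside PFKFB3 (chromosome 10, 6151217 to 6151888). Further SG regions were assigned to the cytoskeletal and adhesion genes ACTN1, FERMT2 and RHOB, and to CDKN2B, KRT14 and PMAIP1. SG regions were assigned to 10 of 22 hypoxia and glycolysis genes, including HIF1A, VEGFA and HK2, and to 10 of 26 integrin and focal adhesion genes, including VCL and PTK2. They were assigned to 10 of 25 mesenchymal stromal genes, including COL1A2 and PRRX1, 9 of 24 TGF-beta genes, including TGFBR1 and SMAD3, and 3 of 26 chondrogenic genes (ACAN, COL11A2 and WWP2). Apoptosis and p53 genes had 8 of 22, AP-1 genes 7 of 23 and adipogenic genes 6 of 16, and the other lists given here 1 to 6 members. Over all protein-coding genes it was 2235 of 19974. That share is not a like baseline, since some lists held more peaks per locus than the average gene. Relative to it they held 2.80 (integrins), 2.36 (TGF-beta), 1.54 (hypoxia) and 1.48 (stromal). Relative to all genes, log2 differences of SG from CG at 16 h were −0.02, 0.04, 0.09 and 0.00 for these lists. The counts of assigned genes were not tested, and the example genes were chosen after their values were seen.

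The highest ranked CG regions at 16 h were assigned to ASB13, NFIB, PPIAP59, CDKL3, PPIAL4F and ARMH3. At 48 h the ARMH3 region had a peak in 3 SG and 3 CG libraries and NFIB in 2 SG and 2 CG. The other regions of these had a peak in CG libraries alone at 48 h. PPIAL4F belongs to a family of near-identical copies, so its assignment is uncertain. A CG region lay inside SOX6, a partner of SOX9 in cartilage (hg38, chromosome 11, 15988792 to 15989234). Another lay 1096 bp from a gene end of the adhesion gene ICAM1 (chromosome 19, 10269575 to 10270024). Others were assigned to the nuclear envelope genes TMPO and TOR1AIP1, and to SESN1, CXCL8, LTBP2, LAPTM5, AXIN2 and MKI67. Of the SG regions 9.56% lay at gene ends, and of the CG regions 4.93%. With 2 libraries per group there are only 3 splits, too few for a share under 0.05, and the highest other split gave 3700 regions against the observed 4464. The SG count was 9319 without SG replicate 1, 6356 without CG replicate 1 and 7448 without CG replicate 2. The CG count was 3782 without SG replicate 2, 1103 without SG replicate 1, 2238 without CG replicate 1 and 2143 without CG replicate 2. With equal list length the counts were 1009 SG and 1049 CG regions.

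Across both times, 5 regions were present in all SG and no CG libraries, and 16 in all CG and no SG libraries. Of the SG regions, 1 lay inside the translation factor gene CTIF (hg38, chromosome 18, 48834700 to 48834960), and others were assigned to EEF2, PIGU and GNAQ. A CG region lay inside the neuronal growth gene GAP43 (chromosome 3, 115699849 to 115700284), and others were assigned to TMEM169, ADK, CHST4, STAB2 and TMEM178A. The STAB2 region lay inside NT5DC3. Of 60 splits made within time, 25 separated at least 21 regions, and the highest other split separated 208. With equal list length 2 of 60 splits separated at least 37 regions (highest other 44), and scaled per bp of width 2 of 60 separated at least 88 (highest other 92). Under the strict threshold and with equal list length, 0 of the 4 named SG and 0 of the 6 named CG regions remained separated, and after scaling 0 and 4. The SG count was 51 without SG replicate 3 at 48 h, and the CG count was 73 without SG replicate 2 at 16 h. The SG count ranged from 6 to 51 and the CG count from 18 to 73 with each library left out. These counts rose under a looser rule, so a rise alone does not show dependence on 1 library. Between libraries of the same gel the Jaccard index was 0.512 ± 0.0353 (n = 2 pairs) at 16 h and 0.442 ± 0.0885 (n = 6 pairs) at 48 h. Between gels it was 0.515 ± 0.0125 (n = 4 pairs) and 0.451 ± 0.0885 (n = 9 pairs), a mean difference of −0.0107 (exact permutation p = 0.8). This difference was 0.00558 without SG replicate 1 and 0.00250 without SG replicate 2 at 48 h.

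Loci of the apoptosis and p53 list held 3.18 ± 0.514 peaks in SG and 2.45 ± 0 in CG at 16 h (n = 2 each), and 2.62 ± 0.579 and 2.77 ± 0.516 at 48 h (n = 3 each). Relative to all genes, the log2 difference of SG from CG over both times was 0.15 (exact permutation p = 0.0167, adjusted p = 0.483). With equal list length it was 0.00 (exact permutation p = 0.95), and under a strict threshold 0.11 (exact permutation p = 0.183). On lists scaled to the lowest background it was 0.18 (exact permutation p = 0.0167, adjusted p = 0.242). Scaled per bp of width it was 0.10 (exact permutation p = 0.05). The exact permutation p on lists scaled to the lowest background ranged from 0.0167 to 0.0333 with each library left out. Loci of the chondrogenic list held 3.17 ± 0.626 peaks in SG and 2.58 ± 0.272 in CG at 16 h (n = 2 each), and 2.27 ± 0.933 and 2.87 ± 0.851 at 48 h (n = 3 each). Its log2 difference was −0.07 (exact permutation p = 0.7), and −0.08 with equal list length (exact permutation p = 0.333). After scaling it was −0.28 (exact permutation p = 0.0333, adjusted p = 0.242). This scaled exact permutation p was 0.0833 without any 1 of the 3 CG libraries of 48 h. Without SG replicate 3 at 48 h the chondrogenic value as deposited was 0.04. At 48 h, 7.67 ± 1.53 of the 26 chondrogenic genes had a gene-end peak in SG and 10.3 ± 1.15 in CG (n = 3 each), and at 16 h 10 ± 0 in SG and 10 ± 1.41 in CG (n = 2 each). Exact permutation tests called 0 of the 29 lists after correction, as deposited and after scaling. With a smallest possible p of 0.0167, a list alone at that p has an adjusted p of 0.483, so no single list could be called.

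Among the other lists, the log2 differences were 0.17 for adipogenic genes, 0.15 for AP-1 and immediate early genes, 0.13 for HOX and limb patterning, and 0.11 for mechanosensitive channels. AP-1 genes had an unadjusted exact permutation p of 0.283, which was 0.0333 after scaling at a log2 difference of 0.19. The scaled AP-1 value was 0.10 without SG replicate 3 at 48 h, and its exact permutation p was 0.133 without CG replicate 1 at 48 h. The AP-1 value as deposited was 0.05 without SG replicate 3 at 48 h, and 0.21 without SG replicate 2 at 16 h (exact permutation p = 0.0333). Values were 0.07 for FGF, hedgehog and Notch, 0.06 for ubiquitously expressed genes, 0.04 for inflammatory genes, 0.03 for hypoxia and glycolysis, and 0.02 for YAP/TAZ targets. They were 0.01 for BMP, 0.01 for TGF-beta, and 0.00 each for matrix proteases, histone methylation and cell cycle. Negative values were −0.02 for mesenchymal stromal genes, −0.03 for integrins, −0.05 for glucocorticoid response, −0.06 for histone acetylation, −0.06 for hypertrophic and osteogenic genes, and −0.10 for WNT. Nuclear envelope genes had −0.06, and −0.05 after scaling (exact permutation p = 0.0333, and 0.133 without SG replicate 2 at 16 h). Markers of other cell types had 0.09 (haematopoietic), −0.01 (neural), −0.02 (myogenic), −0.08 (endothelial) and −0.12 (epithelial). After scaling, values were 0.04 for adipogenic genes, 0.00 for HOX, 0.01 for mechanosensitive channels and −0.29 for endothelial markers. Directions turned for FGF, hedgehog and Notch (−0.02), YAP/TAZ (−0.03), TGF-beta (−0.02), matrix proteases (−0.01), BMP and glucocorticoid response. Scaled per bp of width, glucocorticoid response kept its direction, while values also turned for adipogenic genes (−0.08, exact permutation p = 0.05), HOX (−0.04), mechanosensitive channels (−0.10), neural (0.07) and haematopoietic markers. With equal list length, values turned for ubiquitously expressed genes (−0.09) and for endothelial (0.04), neural (0.12) and haematopoietic markers (−0.06). They also turned for TGF-beta (−0.07), YAP/TAZ (−0.06), mechanosensitive channels (−0.03), matrix proteases (−0.02), FGF, hedgehog and Notch (−0.01), and histone methylation. Of the 29 lists, only apoptosis and p53 had an unadjusted exact permutation p of 0.05 or less as deposited, and 4 lists (apoptosis and p53, AP-1, chondrogenic and nuclear envelope) did after scaling. With equal list length only ubiquitously expressed genes did (exact permutation p = 0.0333). In those shortened lists AP-1 had 0.14 (exact permutation p = 0.1) and nuclear envelope −0.04 (exact permutation p = 0.267).

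**Figure D3:**
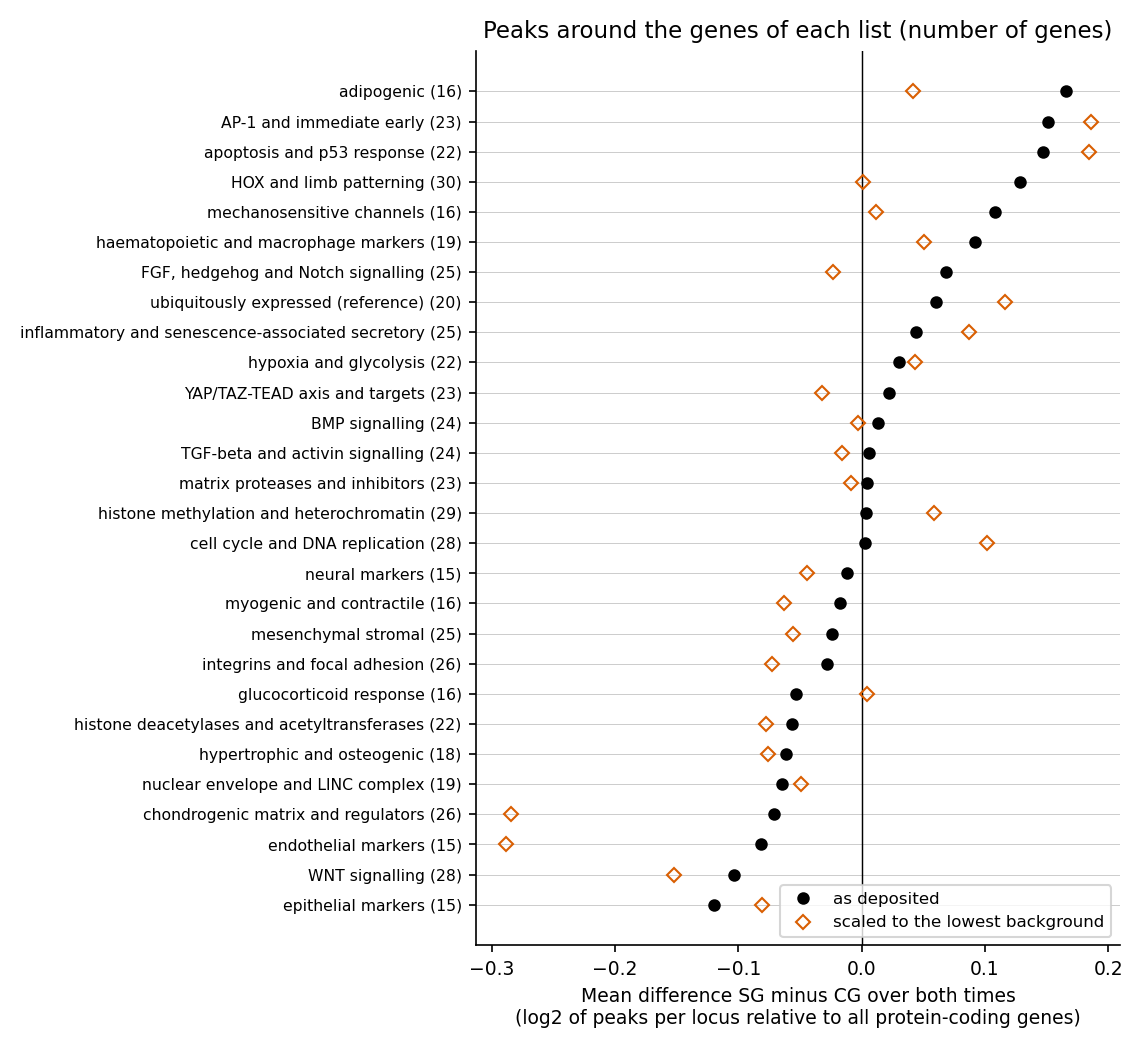
Mean difference between SG and CG over both times in log2 peaks per locus relative to all protein-coding genes, for 28 of the 29 fixed lists with the number of genes in brackets. Filled circles are lists of peaks as deposited and open diamonds are scaled to the lowest background; chondrogenic genes lie at −0.07 and −0.28.

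Adjusted over the list alone, exact permutation tests called 0 members of any list, with 15 members higher and 16 lower in SG at an unadjusted p of 0.05 or less. With a smallest possible p of 0.0167, no member could be called alone, since several of its list would need that p. The genes given here were chosen after their values were seen. The joint gene GDF5 had a relative difference of 0.566 (exact permutation p = 0.0167, adjusted p = 1), with every SG above every CG library of its time. The WNT antagonist gene SFRP1 had −0.652 (exact permutation p = 0.0167, adjusted p = 1), with every SG below every CG library of its time. The glucocorticoid target TSC22D3 had −0.619 (exact permutation p = 0.0167, adjusted p = 1), with the same order of libraries. After scaling, the exact permutation p was 0.2 for GDF5, 0.0333 for SFRP1 and 0.217 for TSC22D3. Over all 18215 genes with a locus peak, exact permutation tests called 0 after correction. At unadjusted p of 0.05 or less, 308 were higher and 295 lower in SG (3.31% of tested genes). No single gene could pass this correction, since the smallest possible p was 0.0167.

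At gene ends, 27.9 ± 6.91% of SG peaks and 22.8 ± 4.25% of CG peaks were found at 48 h (n = 3 each), and 22.8 ± 2.51% and 25.3 ± 0.176% at 16 h (n = 2 each). The SG minus CG differences in percentage points were 5.18 at 48 h (exact permutation p = 0.4), −2.44 at 16 h (p = 0.333) and 2.13 over both times (p = 0.667). Without SG replicate 3 at 48 h, the 48 h difference was 1.19 and the one over both times −0.423. With equal list length the SG share lay 1.81 points above CG over both times (exact permutation p = 0.0333), with all SG above all CG libraries at 16 h, where the difference was 1.04. In these shortened lists the 48 h shares were 35.1 ± 0.899% in SG and 32.8 ± 1.35% in CG (n = 3 each). On scaled lists they were 34.0 ± 3.99% and 25.2 ± 3.81%, a difference of 8.77 points (exact permutation p = 0.1, the smallest possible), with 5.09 over both times (p = 0.117). Genes with a gene-end peak numbered 11726 ± 1096 in SG and 12117 ± 698 in CG at 48 h (n = 3 each), and 12837 ± 669 and 12282 ± 21.2 at 16 h (n = 2 each). The log2 ratios were −0.05 at 48 h (exact permutation p = 0.7) and 0.06 at 16 h (p = 0.333), and the ratio over both times was 0.997 (p = 0.967). Without SG replicate 3 the log2 ratio at 48 h was 0.03, and over both times 0.04. Over both times it was 0.02 without CG replicate 1 at 48 h, and 0.01 without either CG replicate 3 at 48 h or SG replicate 1 at 16 h.

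Between the times, 86 regions were present in all 4 libraries of 16 h and none of the 6 of 48 h, and 15 had the reverse. Regions of 16 h included 1 lying 141 bp from a gene end of TSC22D3, a glucocorticoid target (hg38, chromosome X, 107712391 to 107713080). Whether this end is the start or the far end was not known here, so the region cannot be read as a promoter. Others of 16 h were assigned to NUAK2, a YAP target, to the replication gene MCM3, and to PPP1R12B, A1CF, NFIC and NXPH3. The PPP1R12B region lay inside SYT2. Regions of 48 h were assigned to NALCN, F2RL1, PRICKLE2 and MAP2K6. Of 100 splits made within gel, 16 separated at least 101 regions, with 309 in the highest other split. With equal list length 1 of 100 splits separated at least 145 (highest other 76), but 0 of the 7 named 16 h regions and 1 of the 4 named 48 h regions remained separated. Under the strict threshold 3 of the 7 and 0 of the 4 remained, and on scaled lists 6 and 1. The 16 h count was 289 without CG replicate 1, 224 without CG replicate 2 and 230 without SG replicate 1, all of 16 h. It was 209 without CG replicate 1, 146 without CG replicate 3, 143 without SG replicate 1 and 137 without SG replicate 2, all of 48 h. The 48 h count was 88 without SG replicate 3, 27 without CG replicate 2 and 25 without SG replicate 2 of 48 h, and 40 without SG replicate 2 and 24 without CG replicate 1 of 16 h. The log2 ratio of peak number at 48 h to 16 h was −0.13 (exact permutation p = 0.7), and 0.04 without SG replicate 3 at 48 h. The gene-end share differed by 1.29 points (exact permutation p = 0.75), and by −0.904 without SG replicate 3 at 48 h.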

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

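Tests on scaled lists and the comparison of lost regions with other divisions were chosen after the result was seen, while equal list length, splits and leaving out libraries were chosen before the data were examined. What each explanation predicts was set down with the results known, except for an even loss of signal. Results stood out here for the size of the difference between the gel effects at the times. The permutation of gel labels within time is exact only where the gel has no effect at either time. A low p below can thus come from any gel effect, and does not alone show that the effects differ. On lists scaled to the lowest background, the log2 ratio of SG to CG in peak number at 48 h, minus that at 16 h, was −0.68 (exact two-sided permutation p = 0.0167). On the same lists, the gel difference in the share of peaks at gene ends was 9.20 percentage points larger at 48 h than at 16 h (exact permutation p = 0.05). As deposited, the values were −0.65 (exact permutation p = 0.167) and 7.62 (p = 0.133). With depth per bp of the shortest peak they were −0.66 (exact permutation p = 0.1) and 9.33 (p = 0.117), so both calls depend on how depth is measured.

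For the lower number of peaks in SG at 48 h, scaling gave a log2 ratio of −0.58, which does not bear on depth, since background was 0.964 ± 0.308 fragments in SG and 0.723 ± 0.133 in CG (n = 3 each) and scaling removes more from deeper libraries. As deposited, the ratio of −0.35 was −0.06 without SG replicate 3, so 1 short SG list carried most of that difference. On scaled lists the weakest ratio with 1 SG library left out was −0.47, also without SG replicate 3. This scaled value cannot weigh against a single short list. SG replicates 1 and 2 had the highest background of the 10 libraries (1.07 and 1.21 fragments), where scaling removes most. For an even loss of signal over background, regions in all CG and no SG libraries had a median percentile of 35.6 within the CG lists (quartiles 26.8 to 46.5), against 81.2 for the 20109 regions in all 6 libraries. The 19 other divisions of these libraries gave medians of 19.9 to 35.7, so an even loss and a loss at selected regions could not be told apart. The median fold over local background was 5.86 ± 0.177 in SG and 6.50 ± 0.331 in CG at 48 h (n = 3 each). At 16 h SG had 6.61 ± 0.235 and CG 7.56 ± 0.164 (n = 2 each), although SG held more peaks as deposited. At each time every SG library lay below every CG library, as an even loss would give. Depth was not excluded as a source of this order. At 16 h background was 0.543 and 0.837 fragments in SG and 0.427 and 0.413 in CG. At 48 h SG replicate 3 (0.618) had less background than CG replicates 1 and 3 (0.762 and 0.831), which goes the other way. The median fold was therefore not separated from depth. This median covers only the peaks each library called, so it cannot tell an even loss from a loss at selected regions. The cause of the lower number stays open.

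For the higher share of peaks at gene ends in SG at 48 h, the explanation tested was that shorter lists keep the strong peaks, which lie at gene ends. With equal list length the difference at 48 h was 2.32 points (exact permutation p = 0.2) against 5.18 as deposited, so list length may account for part of it. On scaled lists it was 8.77 points (exact permutation p = 0.1, the smallest possible), with all 3 SG above all 3 CG libraries, and 10.9 with depth per bp. Scaling left a mean of 29816 peaks in SG and 44931 in CG at 48 h, and 25189 and 41169 with depth per bp. Shorter SG lists also predict a larger share, so scaled values cannot weigh against list length. Over both times the difference was 1.81 points with equal list length (exact permutation p = 0.0333), 5.09 scaled (p = 0.117) and 7.13 with depth per bp (p = 0.05), against 2.13 as deposited (p = 0.667). The 16 h part changed sign, from −2.44 as deposited to 1.04 with equal list length, and the cause stays open.

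Separated regions were weighed against other splits of the same libraries. Between gels at 48 h, 4 of 10 splits reached the observed 695 regions (highest other 2666), 2 of 10 reached 521 with equal list length (highest other 550), 2 of 10 reached 1518 on scaled lists (highest other 2180) and 1 of 10 reached 2033 with depth per bp (highest other 1726), too few splits for a share under 0.05. Across both times 25 of 60 splits reached 21 regions (highest other 208), but 2 of 60 reached 37 with equal list length (highest other 44), 9 of 60 reached 51 on scaled lists (highest other 115) and 2 of 60 reached 88 with depth per bp (highest other 92), so this pattern stays open. Between the times 16 of 100 splits reached 101 (highest other 309), against 1 of 100 for 145 with equal list length (highest other 76) and 1 of 100 for 340 on scaled lists (highest other 264). The lists of the 2 times are named by different schemes, so time and a possible sequencing batch cannot be told apart.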

How the results depend on the processing

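Tests on scaled lists were chosen after the results were seen. No gel difference in peak number, covered length or gene-end measures passed p of 0.05 as deposited, and none did under the strict threshold, which kept every direction. The same held for peak number and covered length on chromosomes 1 to 22 only, and for gene-end measures with 500 bp windows. Regions in at least 3 libraries gave 2966 SG and 566 CG regions at 16 h, against 3775 and 689, but the other separated counts already need 3 libraries, so they were not tested by it. Loci with 50 kb margins kept the direction of the 4 lists compared. Where a value moved, the cause was not tested. Strict threshold: separated SG regions numbered 14 at 48 h, 2078 at 16 h and 0 at both times, and 48 h regions 2. Equal list length: the gene-end share over both times was 1.81 points (exact permutation p = 0.0333). The 16 h share (1.04), the share between times (−1.05) and the log2 number of genes with a gene-end peak (0.0457 over both times, 0.0624 at 48 h) reversed. Separated regions (SG and CG) were 199 and 322 at 48 h, 1009 and 1049 at 16 h, and 12 and 25 at both times, with 54 of 48 h. Summit inside and 50% covered: 1188 CG regions at 16 h, 8 SG regions at both times, 3 of 48 h and 147 of 16 h. Scaled to the lowest background: the difference of gel effects was −0.68 (exact permutation p = 0.0167) and the similarity difference 0.00660. Peak number was −0.31 over both times (exact permutation p = 0.167) and −0.40 between times (p = 0.07). The log2 number of genes with a gene-end peak was −0.0501 over both times (exact permutation p = 0.317) and −0.100 at 48 h (p = 0.2). Separated regions were 15 and 1503 at 48 h, 1201 (CG) at 16 h, 0 and 51 at both times, 3 of 48 h and 337 of 16 h. With 1 library left out these ranged from 15 to 94 (SG) and 1503 to 6298 (CG) at 48 h, 1200 to 3988 (CG) at 16 h, 0 to 8 and 56 to 209 at both times, 3 to 29 of 48 h and 358 to 749 of 16 h. Another 48 h split of scaled lists separated 2180. Scaled per bp of width: peak number was −0.45 over both times (exact permutation p = 0.05) and −0.50 between times (p = 0.04), and the gene-end share 7.13 points (p = 0.05). Genes with a gene-end peak were at −0.0911 over both times (exact permutation p = 0.0833) and −0.152 at 48 h (p = 0.1, the smallest possible). Peak number (−0.0565), covered length (−0.0446), share (1.53) and genes with a gene-end peak (−0.000563) at 16 h reversed, as did similarity (0.0139). Separated regions were 6 and 2027 at 48 h, 1824 and 1610 at 16 h, 0 and 88 at both times, 1 of 48 h and 477 of 16 h. With each library left out, covered length ranged from −0.17 to 0.47 at 16 h, −0.60 to 0.0524 at 48 h and −0.30 to 0.10 over both times. Peak number ranged from −0.19 to 0.10 over both times and −0.23 to 0.0393 between times, and the difference of gel effects from −0.87 to −0.36. Genes with a gene-end peak ranged from −0.0960 to 0.0300 at 48 h and −0.0302 to 0.0446 over both times. The share ranged from −0.423 to 3.23 over both times and −0.904 to 2.35 between times, and similarity from −0.0256 to 0.00558. Separated SG regions ranged from 53 to 711 at 48 h, 3774 to 9319 at 16 h and 6 to 51 at both times. CG regions ranged from 636 to 4304, 688 to 3782 and 18 to 73. Regions of 48 h ranged from 15 to 88 and of 16 h from 90 to 289. With a library left out the rule for a separated region is looser, and counts tend to rise. Such ranges, as deposited or scaled, therefore do not measure stability. The AP-1 list ranged from 0.05 to 0.21 and the chondrogenic list from −0.12 to 0.0362. Scaled lists with each library left out gave a difference of gel effects of −0.84 to −0.54 (exact permutation p from 0.0167 to 0.0667). No sign was seen that replicate numbers pair the samples (r of deviations −0.0688 to 0.0474 at the same number, −0.0883 to 0.134 at other numbers). With so few libraries per group, a pairing cannot be excluded, and the labels do not state one. With the replicate block, the apoptosis list stayed at 0.15 with an exact permutation p of 0.0625, the smallest possible there, and 48 h peak number at −0.35 (p = 0.75). No call was possible under the block, so it does not bear on stability. Motif alternatives with other windows were not run, since no genome sequence was used here. Depth of 12 to 16 fragments at the median summit limits calls at weak peaks.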
